A study of Homo sapiens with 6 samples.

How the data were processed

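RNA was sequenced from subcutaneous tumours of a patient-derived melanoma xenograft carried in NSG mice, an immunodeficient strain. Mice received vehicle or bromosporine, an inhibitor of many bromodomains, together with cobimetinib, an inhibitor of the kinases MEK1 and MEK2. The sample titles number 3 tumours per group, 6 libraries in all, and do not say whether the tumours came from separate mice. The labels name no batch, dose or time point.

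The data are 1 deposited table with 15795 rows and 15701 distinct gene symbols. Per the file headers, the authors gave each gene a mean for each group, and the values are on a log2 scale with a lowest deposited mean of 0.0046 and a highest of 12.55. The linear unit is not given in the sources used here. The log2 values are never below 0, so a pseudocount of 1 is presumed, and a log2 difference then understates the change of low genes. STAR and the hg19 genome build are named in the submitters' processing notes, with no role given. Per the file headers, each gene was measured over the exon-exon junctions listed beside it, with a median of 10 junctions per row. Genes whose transcripts have no such junction are therefore not analysed here. Junctions to another gene were used in 804 rows, so those rows can share reads with a neighbour or a paralog. The deposited p-values hold a test of the drug group against control and an analysis of variance, each with an adjusted form. The deposited table also holds the maximum read count of a gene in any library, from 5 to 773930 with a median of 508. The deposited fold column carries the words Insufficient Expression in place of a number in 6370 rows, called marked rows here. No marked-free row had a maximum read count under 210. No values per library were used, because the table holds group means only, and the depth of each library is therefore unknown.

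The planned design assumed a value for each library. Group means and p-values were found instead, so the spread of each gene was recovered from the deposited p-values. The analysis of variance with 4 residual degrees of freedom gives the residual variance of each gene. Recomputing limma's empirical-Bayes moderated test from those variances over all rows gave the deposited p-values to within a relative difference of 3.2e-08. The deposited adjusted p-values equal the Benjamini-Hochberg adjustment over all rows. The main test is the one planned for values that are not counts. It is limma's moderated test, with trend and robust options off, on rows with a mean linear value of at least 1. The linear value was taken as 2 to the power of each deposited mean, minus 1, averaged over both groups. This filter kept 10650 rows with 10611 symbols, of which 1293 are marked rows. The prior degrees of freedom were 5.2 and the total was 9.2. A first pass had used the deposited adjusted p-values over all rows; the fixed filter was restored after the results of both had been seen, and both are reported. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. For calls by the analysis of variance, its deposited unadjusted p-values were adjusted anew over the tested rows. Differences are treated minus vehicle on the log2 scale. Each SE and 95% interval is implied by the deposited p-values, and the median within-group SD of tested rows was 0.11. The 2 groups' p-values measure the spread between 3 tumours per group. Rows were used as deposited in counts, and the row with the highest read count stood for a symbol in gene lists.

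The 22 pathway lists and 8 cell type lists were fixed before the data were examined. They were tested with limma's cameraPR on z-scores of the moderated test, with a preset inter-gene correlation of 0.01, adjusted over the pathway lists. Medians were also set against 10000 random lists matched in 10 level bins and 5 junction bins. Terms for biological process were taken from the annotation column of the deposited table and tested the same way when they held 10 to 400 genes. Terms for cellular component, curated pathways, gene families and transcript classes were looked at during exploration, and of these only transcript classes are reported.

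Genes to name were chosen by a fixed rule. It took the 8 largest rises and the 8 largest falls among changed genes with a mean linear value of at least 1, up to 3 members of each pathway list with the smallest p, and 12 genes always named. The always-named genes include DUSP6, SPRY4, CCND1, HEXIM1, MYC, CDKN1A, BBC3, BCL2L11, BCL2, MITF and MAP2K1. Some genes the rule selects are left out of the text and figures. Loci without a gene symbol and clone-based names were left out, as were genes that could reveal a person's sex. The rule also asked that the 3 treated values lie on one side of the 3 vehicle values, which group means cannot show.

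The recovery of the spread, the main test and the list test were run on simulated data for 10650 genes with 200 changed. The trend removal, the matched random lists and the test of a shared difference among list members were not simulated. Of 100 genes changed by 0.5 on the log2 scale 59 were called, of 100 changed by 1.0 on that scale 92 were called, and 4 of 10450 unchanged genes were called. Of 500 unchanged lists of 18 genes, 2.2% had p under 0.05. Of 200 lists raised by 0.4 on the log2 scale, 100% did. Simulated genes were drawn independently, so these rates do not hold for real lists whose genes vary together. The data called 4210 of 10650 rows, a far larger share than the 200 simulated, and the adjusted p depends on that share. The rates of called genes therefore do not carry over to the data. Nor does the rate for raised lists, which were set against a nearly unchanged background. Alternatives to the filter, threshold, test, centring, rows, preset correlation and a trend were tried. The trend is a cubic regression of the differences on junction number, gene span and level together, so its removal does not separate these 3. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.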

Results

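Tumours of a human melanoma xenograft were compared after treatment of the mice with bromosporine plus cobimetinib or with vehicle, with 3 tumours per group. The study asked which genes differ between the drug and vehicle groups. The drug combination was the only factor, so the part of either drug cannot be separated. The depth of each library is unknown, and the highest read count of any tested gene in a library ranged from 8 to 773930 with a median of 1273. All differences are treated minus vehicle on the log2 scale, with SEs implied by the deposited p-values.

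Treated tumours had lower levels of mitotic, hypoxia-related, glycolytic and respiratory chain genes, and of several genes induced by ERK signalling. They had higher levels of pigment cell genes and of the receptor kinases MET and ERBB3. Of 10650 tested rows, 4210 changed by limma's moderated test, 2324 higher and 1886 lower. Most changes were small, with a median fold of 1.36 among changed genes. At least 1.5-fold was reached by 563 higher and 624 lower genes, and at least 2-fold by 117 higher and 175 lower genes. The authors' deposited table, adjusted over all 15795 rows, holds 4444 changed rows, 2431 higher and 2013 lower. Adding 0.05 to every difference, the log2 ratio of the summed linear values of vehicle to treated, moved the split to 2924 higher and 1548 lower. Linear values themselves were not rescaled, which would move low genes by less. Centring on the median difference, a shift of 0.03, turned the majority the other way, to 1971 higher and 2119 lower.

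The largest rises included the cystatin genes CST1 at 2.93 (SE 0.23), CST2 at 2.71 (SE 0.11) and CST4 at 2.48 (SE 0.15). Cystatins are secreted inhibitors of cysteine proteases. These paralogs lie together on chromosome 20, with CST1 at 23728190 to 23731905, CST2 at 23804406 to 23807368 and CST4 at 23666277 to 23669677 on hg19. CST1 and CST2 were measured partly over junctions to another gene, so their separate levels are uncertain, and CST4 is a marked row. The endothelin receptor EDNRB rose by 2.09 (SE 0.20). The matrix protease MMP2 rose by 1.97 (SE 0.16), the matrix protein MATN2 by 1.94 (SE 0.19) and the phospholipase PLA1A by 1.67 (SE 0.22).

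The largest fall was in VGF, which encodes a secreted neuropeptide precursor, at chromosome 7, 100805790 to 100808874 on hg19. It fell by 4.23 on the log2 scale (SE 0.40), a fold of 18.7, with an adjusted p of 0.000145. The alpha-tubulin gene TUBA8 fell by 3.30 (SE 0.12) and the elongation factor EEF1A2 by 3.10 (SE 0.10). The kallikrein KLK6 fell, at -2.98 (SE 0.13), as did the membrane protease ST14 at -2.98 (SE 0.13) and the tricellular junction protein LSR at -2.70 (SE 0.12). EEF1A2 and KLK6 were measured partly over a junction to another gene, 1 of 8 and 1 of 7, so they can share reads. CFC1 at -2.98 (SE 0.39) and CFC1B at -2.79 (SE 0.35) also fell, but these near-identical copies can share reads and are uncertain as separate genes.

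**Figure D1:**
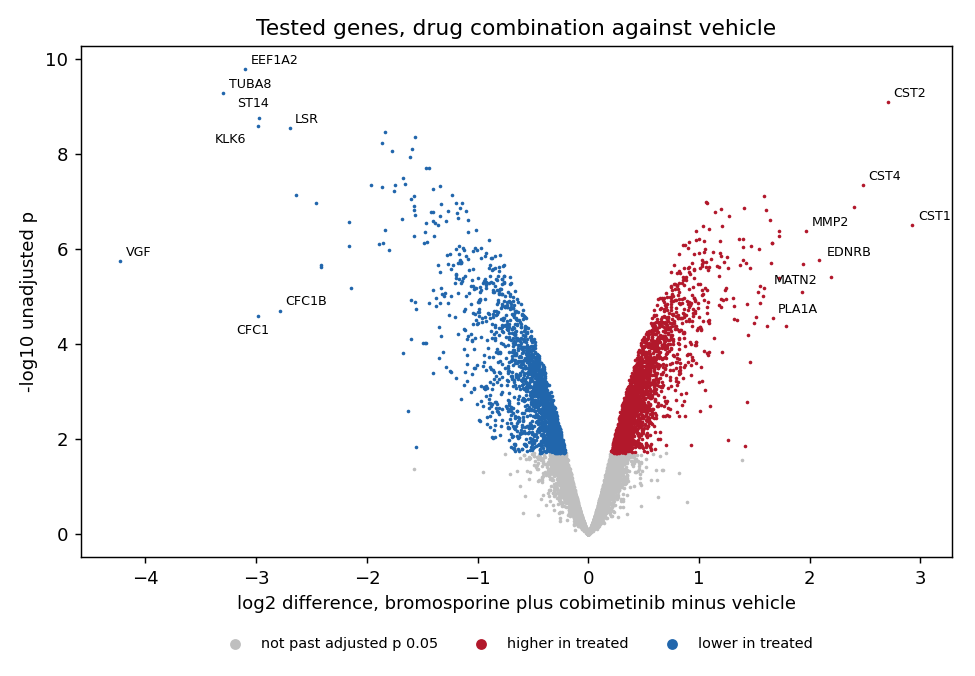
Log2 difference (x axis) against -log10 of the unadjusted p (y axis) for each tested gene, with genes higher in treated tumours in red, lower in blue and the rest grey. VGF lies furthest to the left at -4.23 and CST1 furthest to the right at 2.93.

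**Figure D2:**
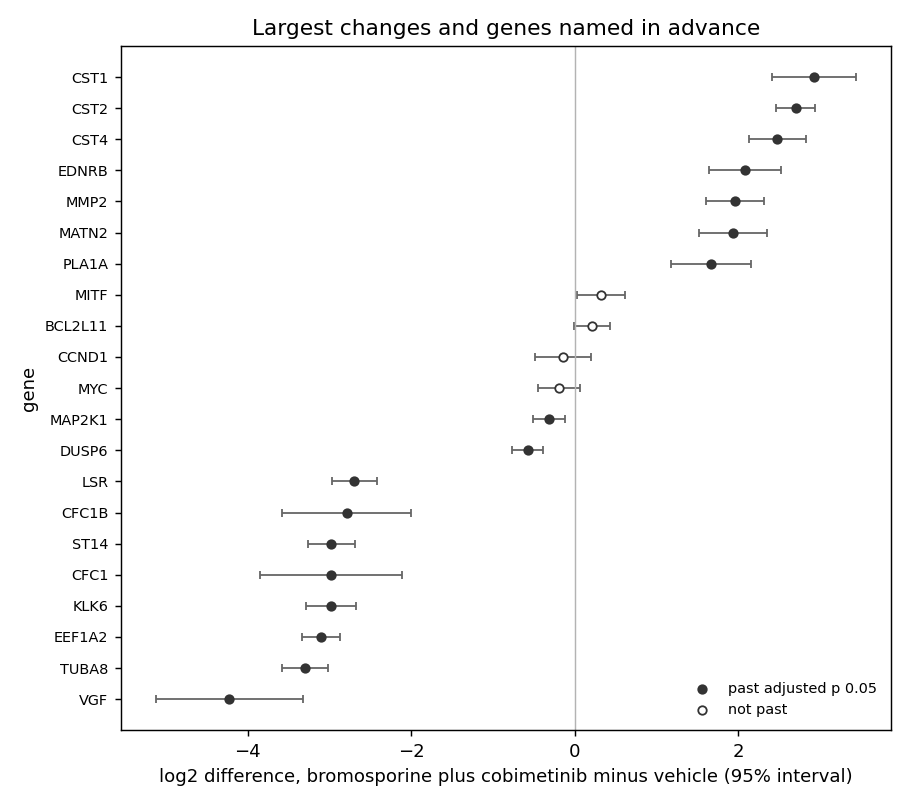
Log2 difference (x axis) with its 95% interval, implied by the deposited p-values, for largest changes and always-named genes that were tested and are named in the text; filled points passed an adjusted p of 0.05. MYC at -0.19 and CCND1 at -0.14 have intervals that include 0.

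Genes of mitosis fell together. Of 22 tested members of the G2/M and mitosis list, 20 fell, none rose and 2 did not pass, with a median of -0.84; adjusted over the list alone, 21 fell. The number of members depends on the test, with 14 lower by the deposited adjusted p-values over all rows. By the deposited analysis of variance p, adjusted anew over the tested rows and without moderated variances, 1 was lower and BIRC5 and KIF20A did not pass. The mitotic kinase PLK1 fell by 1.60 (SE 0.24), the survivin gene BIRC5 by 1.32 (SE 0.21) and the kinesin KIF20A by 1.25 (SE 0.23). In the list test the adjusted p was 1.9e-07. The G1/S and DNA replication list fell less, with a median of -0.31 and 6 of 22 members past the test, all lower; adjusted over the list alone, 5 fell. The polymerase subunit POLA1 fell by 0.50 (SE 0.11), thymidine kinase TK1 by 0.90 (SE 0.21) and the replication factor CDC45 by 0.87 (SE 0.22). Its list test gave an adjusted p of 0.00158, or 0.108 at a preset correlation of 0.1, and by the analysis of variance 0 members passed.

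Of 11 tested cell cycle inhibitors and p53 targets, 1 rose and 2 fell, the same counts when adjusted over the list alone, and the list was not called (adjusted p 0.390). The inhibitor CDKN1C, a marked row, fell by 0.90 (SE 0.15), GADD45A fell by 0.67 (SE 0.11) and the DNA repair gene XPC rose by 0.34 (SE 0.08). CDKN1A lay below the filter and was not tested. Its mean in the authors' deposited table was 0.72 in vehicle and 0.41 in treated tumours.

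Transcripts induced by ERK signalling were mostly lower. Of 15 tested members of the ERK output list, 8 fell, 1 rose and 6 did not pass, the same counts when adjusted over the list alone, with a median of -0.40. The transcription factor ETV4 fell by 1.27 (SE 0.15) and the ERK phosphatase DUSP6 by 0.58 (SE 0.08). The ephrin receptor EPHA4 went the other way and rose by 0.76 (SE 0.10). The list test gave an adjusted p of 0.0148, but 0.0860 without the marked rows and 0.0584 at a preset correlation of 0.05. Over all rows with the deposited p-values, where all 18 members have a row, it was 0.00147. CCND1, which encodes cyclin D1, did not pass, at -0.14 (SE 0.15). SPRY4, EGR1 and EPHA2 were below the filter. The authors' deposited table gives SPRY4 means of 0.41 in vehicle and 0.36 in treated tumours. Chosen after their values were seen, EGR1 had 1.16 and 0.50, and EPHA2 0.76 and 0.31. Their deposited adjusted p-values over all rows were 0.0039 and 0.0073, against 0.512 for SPRY4.

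Of 14 tested RAF-MEK-ERK cascade members, 3 fell and 1 rose; adjusted over the list alone, 3 fell. ARAF fell by 0.44 (SE 0.08), the cobimetinib target gene MAP2K1 by 0.32 (SE 0.09) and the ribosomal S6 kinase RPS6KA1 by 0.34 (SE 0.10). The list was not called (adjusted p 0.213). Receptor tyrosine kinases were higher as a list in the main test, though not in every setting. Of 17 members 8 were tested, and of these 5 rose and none fell, also adjusted over the list alone, with a median of 0.26. Below the filter, and chosen after its values were seen, ERBB4 had deposited means of 0.55 in vehicle and 0.21 in treated tumours. Its deposited adjusted p was 0.0148, while AXL, lower at 0.0611, and INSR, higher at 0.0850, did not pass. MET, the hepatocyte growth factor receptor, rose by 1.64 (SE 0.12), ERBB3 by 0.81 (SE 0.10) and KIT by 0.69 (SE 0.13). The list test gave an adjusted p of 0.0316, and 0.235 over all rows with the deposited p-values. After the joint trend with junction number, gene span and level was removed the adjusted p was 0.0967 and the median 0.18, and the median before removal lay at the 91.2 percentile of matched random lists.

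Genes of bromodomain proteins, the class of protein that bromosporine binds, were slightly higher. Of 27 tested members 9 rose and none fell, the same counts when adjusted over the list alone, with a median of 0.19. The chromatin remodelling subunit PBRM1 rose by 0.61 (SE 0.08), and the acetyltransferases KAT2A by 0.69 (SE 0.10) and KAT2B by 0.47 (SE 0.08). The list test gave an adjusted p of 0.00674, but 0.330 after the joint trend with junction number, gene span and level was removed, and the median lay at the 75.5 percentile of matched random lists.

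Of 3 tested members of the list raised by BET inhibitors, the histone gene HIST1H2BK rose by 0.36 (SE 0.12), and HIST1H2AC at 0.33 and SERPINI1 at 0.21 did not pass. Adjusted over the list alone 0 passed, and the list was not called (adjusted p 0.277). HEXIM1 was not analysed here. The list lowered by BET inhibitors had 4 tested members with a median of -0.38, and 3 fell, also adjusted over the list alone. By the analysis of variance 1 was lower. BCL2, CDK6, E2F2, AMIGO2 and RUNX1 were below the filter and not tested. FOSL1 is also a member of the ERK output list, so its fall is not particular to this list. HMGA2 fell by 0.45 (SE 0.09), FOSL1 by 0.82 (SE 0.19) and SKP2 by 0.32 (SE 0.09), while MYC was at -0.19 (SE 0.11) and did not pass. The list test gave an adjusted p of 0.0365, and 0.0564 over all rows with the deposited p-values. Of 19 tested MYC targets, 1 rose and 3 fell; adjusted over the list alone, 1 rose and 2 fell. Ornithine decarboxylase ODC1 fell by 0.56 (SE 0.10), the transferrin receptor TFRC fell by 0.64 (SE 0.16) and the pyrimidine enzyme CAD rose by 0.51 (SE 0.09), and the list was not called (adjusted p 0.281).

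Pigment cell genes rose, though not all of them. Of 18 tested melanocyte lineage members, 9 rose, 1 fell and 8 did not pass, the same counts when adjusted over the list alone, with a median of 0.37 and an adjusted p of 0.00282 in the list test, or 0.108 at a preset correlation of 0.1. The melanin enzyme DCT rose by 1.19 (SE 0.11), the melanosome transporter OCA2 by 1.06 (SE 0.10) and EDNRB by 2.09 (SE 0.20). The lineage factor MITF was at 0.32 (SE 0.13) and did not pass. Chosen after their values were seen, tyrosinase TYR fell by 0.44 (SE 0.15), and PMEL, the highest gene in both groups, was at -0.07 (SE 0.09). The call for TYR was lost with the deposited adjusted p over all rows (0.0883), and by the analysis of variance 0 members of the list were lower.

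Of 10 tested dedifferentiated melanoma genes, 2 rose and 5 fell, also adjusted over the list alone, with a median of -0.38; by the analysis of variance 0 passed, and the list was not called (adjusted p 0.165). The nerve growth factor receptor NGFR fell by 0.73 (SE 0.14), the matrix enzyme LOXL2 fell by 0.72 (SE 0.16) and TEAD1 rose by 0.39 (SE 0.11). Among fibroblast markers COL6A3 also fell, by 0.67 (SE 0.23), while COL1A1 at -0.62 (SE 0.23) did not pass. A xenograft holds mouse stroma and mouse reads can align to the human genome, so the species behind these markers is unknown. Of 5 tested fibroblast markers 1 fell; adjusted over the list alone, 4 fell, and the list test gave an adjusted p of 0.185.

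Hypoxia-related and glycolytic genes fell strongly. Of 15 tested members 11 fell, 1 rose and 3 did not pass, the same counts when adjusted over the list alone, with a median of -0.73 and an adjusted p of 3.8e-05, or 3.3e-05 after the joint trend with junction number, gene span and level was removed. The angiogenic factor VEGFA fell by 1.34 (SE 0.08) and the glucose transporter SLC2A1 by 1.15 (SE 0.12). The prolyl hydroxylase EGLN3 rose by 0.92 (SE 0.09). Oxidative phosphorylation genes fell by less. Of 17 tested members 10 fell and none rose, also adjusted over the list alone, with a median of -0.26 and an adjusted p of 0.000188. The complex III subunit UQCRC1 fell by 0.67 (SE 0.09), the ATP synthase subunit ATP5B by 0.44 (SE 0.08) and the complex II subunit SDHB by 0.47 (SE 0.09). After the joint trend with junction number, gene span and level was removed, the median was -0.12 and the adjusted p 0.0467.

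Of 14 tested sterol synthesis genes, 1 rose and 3 fell; adjusted over the list alone, 3 fell. DHCR7 fell by 0.58 (SE 0.10) and INSIG1 by 0.40 (SE 0.10), and the list was not called (adjusted p 0.288). Of 11 unfolded protein and integrated stress response genes, 1 rose and 4 fell; adjusted over the list alone, 1 rose and 5 fell. HERPUD1 fell by 0.56 (SE 0.09), TRIB3 fell by 0.58 (SE 0.10) and PPP1R15A rose by 0.25 (SE 0.08), with an adjusted p of 0.213 in the list test. Of 16 lysosome and autophagy genes 2 rose and 6 fell; adjusted over the list alone, 2 rose and 7 fell. LAMP1 fell by 0.46 (SE 0.09), WIPI1 rose by 0.40 (SE 0.08) and GABARAPL1 rose by 0.47 (SE 0.09), and the list was not called (adjusted p 0.221).

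Interferon response genes were higher as a list, with a median of 0.36 over 11 tested members. Of these 5 rose and 1 fell; adjusted over the list alone, 7 rose and 1 fell. The signalling factors STAT2 and IRF9, which act together, rose by 1.36 (SE 0.11) and 1.05 (SE 0.09), and the RNA sensor DDX58 by 0.46 (SE 0.08). The list test gave an adjusted p of 0.0370, but 0.0521 on ranks and 0.0666 without the marked rows. Of 9 tested antigen presentation genes, 2 rose and 1 fell, also adjusted over the list alone, and the list was not called (adjusted p 0.643). The peptide transporter TAP2 rose by 0.46 (SE 0.07), HLA-E rose by 0.31 (SE 0.09) and HLA-C fell by 0.51 (SE 0.10), though HLA genes share reads and are uncertain. Of 15 inflammatory and NF-kB targets 6 were tested, and 3 of these fell, also adjusted over the list alone. These were ICAM1 at -0.38 (SE 0.09), CCL20 at -0.45 (SE 0.13) and RELB at -0.30 (SE 0.10), and the list was not called (adjusted p 0.163). Among the 6 tested targets, 2 were lower by the deposited adjusted p-values over all rows, and 0 by the analysis of variance. CXCL1, below the filter and chosen after its values were seen, went the other way. Its deposited means were 0.45 in vehicle and 1.16 in treated tumours, with a deposited adjusted p of 0.0201.

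Beside these immune lists, all 3 tested myeloid markers changed. As for the fibroblast markers, mouse reads can enter the values of all markers here, which cannot be assigned to human or mouse cells. FCER1G fell by 1.69 (SE 0.13) and LYZ by 0.88 (SE 0.09), both marked rows, while CD68 rose by 0.75 (SE 0.09). The endothelial marker ENG rose by 0.45 (SE 0.11), and the keratinocyte marker KRT10 fell by 0.59 (SE 0.09). The muscle actin ACTA1 did not pass, at -0.59 (SE 0.61). None of the cell type lists was called, with adjusted p of 0.242 for myeloid, 0.268 for endothelial, 0.185 for keratinocyte and 0.636 for muscle markers. The endothelial, keratinocyte and muscle lists had 1 tested gene each, so their list tests say little about the cell type. No lymphoid, erythroid or adipocyte marker passed the filter.

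Of 7 tested pro-apoptotic BCL2 family genes 1 fell, also adjusted over the list alone. PMAIP1, which encodes NOXA and is a marked row, fell by 0.64 (SE 0.12), and BCL2L11, which encodes BIM, was at 0.21 (SE 0.10) and did not pass. Of 6 pro-survival factors 1 rose and 1 fell; adjusted over the list alone, 2 rose and 1 fell. BCL2A1 rose by 0.52 (SE 0.13) and BIRC5 fell by 1.32 (SE 0.21). For BCL2A1, 1 of 4 junctions runs to another gene, so it can share reads. By the analysis of variance 0 members of either list passed. The lists had adjusted p of 0.342 and 0.438, and for the pro-survival factors the median was 0.18 and the test direction up while the mean was -0.02. BBC3 and BCL2 were below the filter and not tested.

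**Figure D3:**
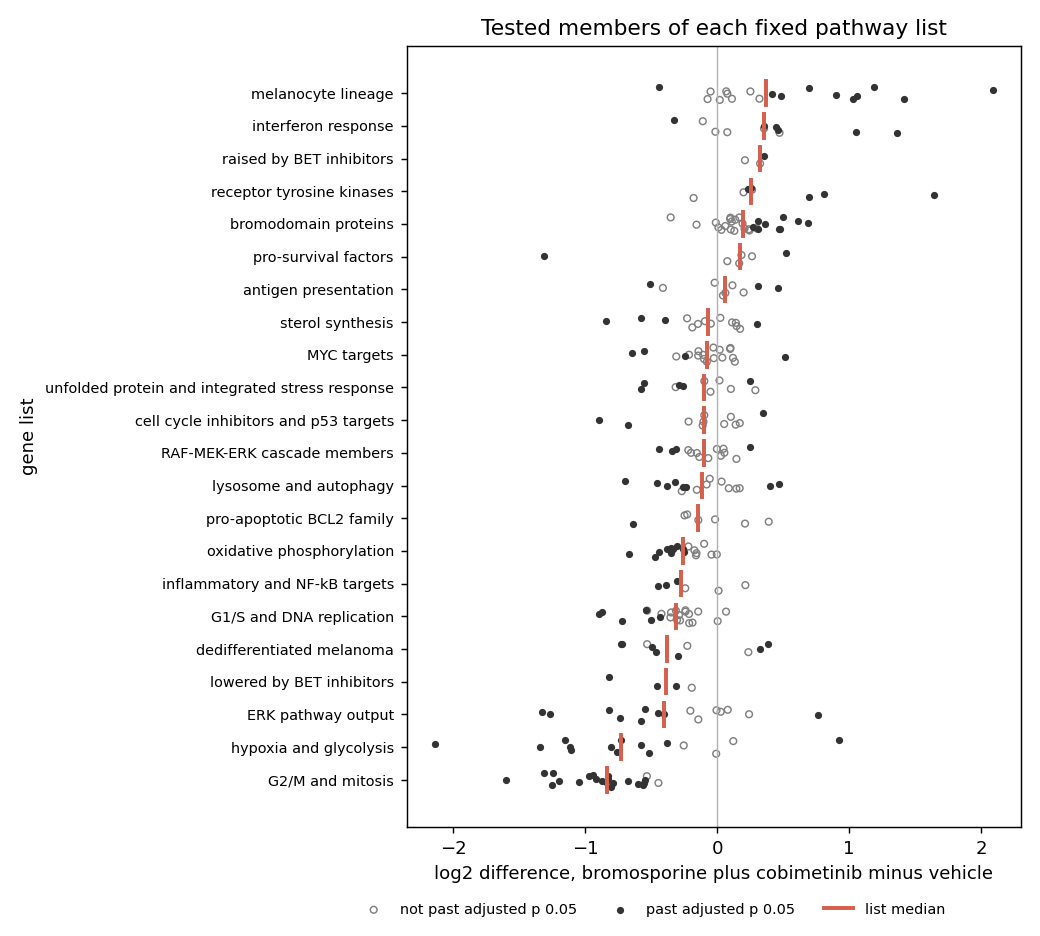
Log2 difference (x axis) of each tested member of each pathway list (y axis), with filled points past an adjusted p of 0.05, open points not past it and a bar at the list median. The medians run from -0.84 for G2/M and mitosis to 0.37 for the melanocyte lineage.

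Cytosolic ribosomal proteins took 13.2% of the summed linear values in the vehicle means and 15.5% in the treated means of the authors' deposited table. Of 82 tested ribosomal protein genes 20 rose and 1 fell; adjusted over the list alone, 13 rose and 1 fell, with a median of 0.19 and an unadjusted p of 0.000472 in the list test. After the joint trend with junction number, gene span and level was removed the median was 0.33 and the p 1.2e-10, while a preset correlation of 0.1 without that removal gave 0.118. The 20 highest genes took 12.7% and 12.1%, and PMEL alone 2.17% and 2.13%. With 1 mean per group these shares carry no error and were not tested.

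The list tests used a preset inter-gene correlation of 0.01, and an estimated correlation could not be computed from group means. Of 10 called lists, 5 kept the call at a preset correlation of 0.05. At a preset correlation of 0.1 there were 3, with adjusted p of 0.00707 for G2/M and mitosis, 0.0151 for hypoxia and glycolysis and 0.0359 for oxidative phosphorylation.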

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

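Tests with centring, the shift for equal sums, the analysis of variance, preset correlations, ranks and unfiltered lists were chosen after the data were seen. So were 1 row per symbol, rows without marks and removal of a joint trend with junction number, gene span and level. The unfiltered count, the stricter filter and both thresholds were planned. The 4210 changed genes (2324 higher, 1886 lower) became 2228 (1185 higher, 1043 lower) at an adjusted p under 0.01. An unadjusted p under 0.05 with 1.5-fold gave 1198 (570 higher, 628 lower), and the analysis of variance p gave 2433 (1365 higher, 1068 lower). A mean of at least 5 tested fewer genes and gave 1500 higher. The other counts were within 1.5 times, from 3630 with the trend removed to 4472 with the shift for equal sums. Centring on the median difference, however, made falls the majority (1971 higher, 2119 lower). With the deposited p-values over all rows 3748 genes were called in both, in the same direction. No called list and no named gene that passed the main test reversed. The myeloid markers, not called, went from down to up without marked rows, where only CD68 is left (adjusted p 0.104). G2/M, hypoxia and oxidative phosphorylation kept their list calls in every setting tried, changed 1 at a time, with preset correlations up to 0.1. Oxidative phosphorylation had an adjusted p of 0.0467 with the trend removed. A stronger correlation between members, or a combination of settings, was not tried. By the analysis of variance p, however, 1 of 22 G2/M members passed, against 20. Adjusted p at a preset correlation of 0.05 was 0.0584 for ERK output, for bromodomain proteins and for the list lowered by BET inhibitors, 0.0596 for receptor tyrosine kinases and 0.0892 for interferon response. At 0.1 these were 0.141, 0.159, 0.111, 0.141 and 0.167, with 0.108 for G1/S and for melanocyte lineage and 0.118 for ribosomal proteins. Without marked rows ERK output had 0.0860 and interferon response 0.0666, and on ranks interferon response had 0.0521. With the trend removed bromodomain proteins had 0.330 and receptor tyrosine kinases 0.0967. Unfiltered, receptor tyrosine kinases had 0.235 and the list lowered by BET inhibitors 0.0564. The cause was not tested. Of 340 values for named genes under alternatives, 30 lost and 2 gained the call, and 21 of those losses were with the analysis of variance p. The 100 highest genes took 27.5% in vehicle and 27.9% in treated means. No paired analysis was possible because the columns are group means and carry no replicate numbers. For the same reason other scalings of libraries, DESeq2, limma-voom, another pseudocount, sums per symbol, leaving out replicates, an estimated correlation, fry and other splits of the samples were not run.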

Other observations

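Only the matched-list test for oxidative phosphorylation was written before its result was seen; the other tests here were chosen after theirs. Among 775 biological process terms of the deposited annotation, 32 were called by cameraPR, 10 higher and 22 lower. The respiratory electron transport chain was the strongest, with 48 of 79 tested genes lower, none higher, a median of -0.32 and an adjusted p of 1.6e-10, or 0.00482 after the joint trend with junction number, gene span and level was removed. With that removal NADH to ubiquinone transport went from 1.9e-05 to 0.0820, mitochondrial ATP synthesis from 0.0117 to 0.540 and aerobic respiration from 0.0435 to 0.190. The tricarboxylic acid cycle had 13 of 27 genes lower and none higher (adjusted p 0.00823). Cilium morphogenesis was higher, with 22 of 36 genes up and 2 down, a median of 0.30 and an adjusted p of 0.00258, or 0.0225 after the removal, but cilium assembly went from 0.00792 to 0.150. Extracellular matrix organization was lower, with 31 of 78 genes down and 11 up (adjusted p 0.0383).

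Pseudogenes that passed the test were mostly higher, which was noticed after the values were seen and not tested as a group. Of 133 tested transcribed unprocessed pseudogenes 57 rose, 10 fell and 66 did not pass, and of 134 unprocessed pseudogenes 43 rose, 5 fell and 86 did not pass. Of 9645 protein-coding genes 2054 rose and 1739 fell. Reads shared with parent genes were not examined. HNRNPA0 had the widest recovered within-group SD, 1.25, and did not pass at -1.57.

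Across tested genes the difference rose with the number of junctions, with medians of -0.06 for 1 to 7 junctions and 0.17 for 30 to 177, and a Spearman rho of 0.23 across genes, which are not independent replicates. A joint trend with junction number, gene span and level is a candidate explanation for the higher bromodomain list, whose genes have a median of 32 junctions. Removing all 3 together lowered the median from 0.19 to 0.07 and gave an adjusted p of 0.330, so most of the list's shift went with the 3 jointly. RNA integrity or coverage could differ between groups, and so could transcription of long genes under the drugs; group means leave both open.

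The lower oxidative phosphorylation list was set against the same joint trend and against a few abundant genes taking more of the reads. Removing the trend moved the median from -0.26 to -0.12 and left an adjusted p of 0.0467, so how much of the fall goes with the trend cannot be told apart here. Abundant genes taking more reads would lower other genes of the same level alike. The list's median of -0.2617 lay at the 1.94 percentile of matched random lists, just outside their central range of -0.2535 to 0.0951. Random lists do not keep genes that vary together, so this percentile can be too extreme and does not decide the question. The 20 highest genes took 12.7% in vehicle and 12.1% in treated means. The 100 highest took 27.5% and 27.9%, and cytosolic ribosomal proteins 13.2% and 15.5%. These shares point both ways and carry no error, so the explanation is left open.

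The higher melanocyte lineage list kept a median of 0.40 and an adjusted p of 0.00195 after the joint trend was removed, which argues against the trend as the whole cause for this list. Overlapping annotation terms lost their calls when it was removed, melanocyte differentiation going from an adjusted p of 0.0383 to 0.0649 and pigmentation from 0.0383 to 0.0517. A larger share of tumour cells, if it were the only change, would raise all members by a similar fold. They moved apart, from 2.09 for EDNRB to -0.44 for TYR, whose call was lost over all rows. Cochran's Q was 376 with p of 1e-05, the smallest that 100000 draws can give. The test rejects only a single shared difference, so a larger share together with changes of separate genes is left open. With a presumed pseudocount, an equal fold also gives smaller differences for low genes. Whether cells changed their transcription or cells of another lineage state were selected was not tested.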
